A study of Homo sapiens with 4 samples.

How the data were processed

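The series measured, by chromatin immunoprecipitation and sequencing (ChIP-seq), where the protein OLA1 lies on DNA in cultured human pulmonary artery endothelial cells. OLA1 (Obg-like ATPase 1, also named GTPBP9) is a nucleotide-hydrolysing protein of the Obg family. Its 4 samples are each a group of 1 by title: an IgG negative control, an OLA1 control, OLA1 with hydrogen peroxide, and OLA1-NLS. Per the labels' protocols, cells were transfected with OLA1-NLS constructs for 24 h, rested for 24 h, exposed to 100 µM hydrogen peroxide for 30 min and fixed in 1% formaldehyde for 10 min. The treatment label names peroxide for all 4 samples, while only 1 title does. The transfection label reads OLA1NLS for the peroxide and NLS samples and WT for the other 2, although the protocol text is the same for all 4. Processed files of the peroxide and NLS samples were used; peak lists of the IgG and OLA1 control samples were not analysed here.

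Each of these 2 samples has a peak list and an annotated copy of it. The files were compared byte for byte, and the 2 peak lists were identical, as were the 2 annotated lists. They were therefore treated as 1 list, and no comparison of the 2 groups could be made. Per the file headers, both copies were called from a library named H2O2_T325D_1 against an input named H2O2_T325D_Input_1. In the usual notation T325D is a change of threonine to aspartate at residue 325, but no label used here ties this name to a sample. The list is called "the deposited list" below, since the sample it belongs to is uncertain.

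Per the file headers, the authors called peaks with MACS 2.2.6 in paired-end mode, with duplicates removed, an effective genome size of 2.7 Gb, a q-value limit of 0.05, narrow peaks and several summits per region. The headers give 5400323 fragments for the immunoprecipitated library and 6717630 for the input after filtering, and a fragment size of 205 bp. Each was called from 1 alignment file, so no replicates were pooled. The alignment folders in the headers are named for bwa mem and hg19, whereas the submitters' processing notes name Bowtie 1.1.2 and hg19. The tool that added genes, region classes and distances is not given in the sources used here.

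The deposited pileup signal is the number of fragments covering the summit in MACS output. The fold enrichment is the authors' ratio of pileup to local input background, with a pseudocount of 1 on each side. The authors' p-value and q-value are deposited as −log10. The authors' distance to the nearest transcription start site (TSS) is in bp. Starts in the annotated list are 1 bp higher than in the peak list, so positions are those of the peak list, 1-based, in hg19. Per-peak values are the authors' and serve only to describe and rank regions within the list.

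The local input background was recovered here as (pileup + 1)/fold − 1. Recomputing each summit's upper-tail Poisson p from it gave the deposited −log10 p to within 6.08e-05 in all 91 regions. MACS takes this background as the highest of a genome-wide value and of the input in windows up to 10000 bp around the summit. Input was scaled to the smaller library by 0.804. Its lowest value was 0.418 fragments, against 0.410 from the header's fragment number, fragment size and genome size, and input is given as a multiple of the lowest value. In 38 regions the background was a whole number of input fragment ends in a fragment-sized window (within 0.001).

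Only chromosomes 1 to 22 were analysed, because the cells are primary human cells; the plan had left out only chromosome Y. Summits sharing a region were merged, keeping the summit with the highest −log10 q, and regions within 100000 bp were joined into loci. Shares carry exact (Clopper-Pearson) 95% intervals and pileups exact Poisson intervals, which cover counting error only. The intervals of shares treat regions as independent, although 42 of 91 share a locus with another, so they are likely too narrow. The limit given for a count of 0 is 3 counts of the total. With 1 library per group nothing here has a replicate check. Grouping of regions was tested against 1000 uniform placements over 2.7 Gb. Gene lists were tested with a one-sided Fisher's exact test of the nearest genes, with Benjamini-Hochberg adjustment. The background was 56752 autosomal genes of a RefSeq gene table (GRCh38.p14), used for names and gene types and not for positions. The authors drew nearest genes from another annotation, which may not hold all of these genes. Counts and shares expected from the table are therefore approximate. Of 59 nearest gene identifiers, 56 matched that table. Local input of loci was compared with a two-sided permutation test of 100000 resamples, or 5000 where each locus in turn was left out. Both tests across many items were tested on simulated data. With nothing planted, 1.5% of 200 simulated sets of 91 regions were called grouped and 0.5% of 200 sets of 56 genes gave a list call. With 3 regions planted beside others, or 3 list genes, 100% were called.

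The gene lists, the main tests and the rule for named regions were fixed before the data were examined. The rule took the 15 regions with the highest −log10 q, the 10 nearest to a TSS, and every region whose nearest gene was on a fixed list, and it called a region by position if its TSS was over 100000 bp away. A further part, the 5 strongest regions unique to each list, named none because the lists were identical. The rule gave 21 regions, 4 of them under both parts. Input levels, the tests of grouping and gene types were added after seeing the list. No genome sequence or hg19 annotation was used, so motifs, base composition, random placements against annotation classes and tests against chromosome length were not run. Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, matplotlib 3.10.9 and bedtools 2.31.1 were used.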

Results

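The series set out to map the contacts of OLA1 with DNA and to look for binding motifs. The deposited list held 91 regions on the autosomes, with 102 summits, on 16 of the 22 autosomes. It was called from 5400323 immunoprecipitated and 6717630 input fragments. The regions covered 32467 bp in total and had a median width of 266 bp (range 205 to 1575). Their median summit pileup was 14 fragments, with a lowest value of 6, and their median fold enrichment over input was 5.64 (range 2.07 to 23.3). In 28 regions fewer than 10 fragments covered the summit. The q-value limit of 0.05 held for the whole call, not for these 91 regions, so it gives no number of false ones here.

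The design implies a comparison of OLA1 after peroxide with OLA1-NLS. It could not be made, because the peak lists under the 2 labels were identical: 91 of 91 regions had the same position, annotation and values. The list stands for 1 library, named H2O2_T325D_1 in its header. The overlap of 100% is that of a list with itself and measures no agreement between libraries. The IgG and OLA1 control samples are not analysed here, so each value below is a contrast of this library with its own input.

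The regions with the largest fold enrichment lay in S100A8, MALAT1 and S100A9. S100A8 and S100A9 encode the subunits of calprotectin, a calcium-binding protein abundant in neutrophils, and MALAT1 is a nuclear long non-coding RNA. The S100A8 region (chromosome 1, 153362519 to 153363034, 630 bp into the gene from its TSS) had a 23.3-fold enrichment and 32 fragments at its summit (95% interval 21.9 to 45.2). The S100A9 region (chromosome 1, 153333118 to 153333447) lay within the gene, 2789 bp from its TSS, with an 18.3-fold enrichment and 25 fragments (16.2 to 36.9). The MALAT1 region (chromosome 11, 65266520 to 65267223) began 1288 bp after the TSS, with a 22.7-fold enrichment and 33 fragments (22.7 to 46.3). Local input at S100A8 and S100A9 was at the lowest level in the list, 0.418 fragments, and at MALAT1 it was 1.19 times that level.

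Among regions over background input, 2 intergenic regions came next. The region on chromosome 4 from 190155020 to 190155225 lay 706749 bp from the nearest TSS and had a 17.6-fold enrichment with 24 fragments (15.4 to 35.7). The region on chromosome 9 from 44876095 to 44876426 lay 113810 bp from the nearest TSS and had a 13.4-fold enrichment with 18 fragments (10.7 to 28.4). CDC27, which encodes a subunit of the anaphase-promoting complex, held 3 regions within 1.76 kb on chromosome 17. The strongest of them (45214436 to 45214641) was in exon 14 of 19, with a 10.7-fold enrichment and 27 fragments (17.8 to 39.3) over an input of 3.85 times the lowest level. The other 2 lay in intron 14 of 18, with enrichments of 5.93 and 9.97 over inputs of 7.69 and 2.88 times that level.

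The highest significance went to ROCK1P1, a pseudogene of the kinase gene ROCK1, at the start of chromosome 18. Its region from 107875 to 109449 covered the TSS and had a −log10 q of 96.5 with 304 fragments at the best summit (271 to 340), but its fold enrichment was 4.70. A second ROCK1P1 region (110224 to 110898) had 125 fragments and a 3.43-fold enrichment. Local input was 153 times the lowest level at the first and 85.6 times at the second. LINC00960, a long non-coding RNA on chromosome 3, had a region 2680 bp upstream of its TSS (75718080 to 75718752) with 81 fragments (64.3 to 101) and a 6.92-fold enrichment over an input 26.0 times the lowest level. HFM1, a helicase gene of meiosis, held a region in intron 4 of 38 (chromosome 1, 91852783 to 91853134) with a 6.07-fold enrichment over an input 17.3 times that level.

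Local input was raised in part of the list. In 33 of 91 regions (36.3%, 95% interval 26.4 to 47.01) local input was at least 5 times the lowest level, and 27 regions lay below 1.5 times it. The count depends on this limit: it was 57 at 2 times and 24 at 10 times. The raised regions had a median of 37 fragments and a median fold enrichment of 5.18, and no fold above 8.67. The regions below 1.5 times had a median of 8 fragments and a median fold enrichment of 6.35, and 21 of them rested on fewer than 10 fragments. The pseudocount of 1 lowers fold most over low input, so the fold medians are not directly comparable. Of the 15 regions with the highest −log10 q, 9 had raised input, among them ROCK1P1, LINC00960, HFM1, ANKRD30BL and a region near FAM27C, and 5 were below 1.5 times. CDC27 was the remaining region.

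**Figure D1:**
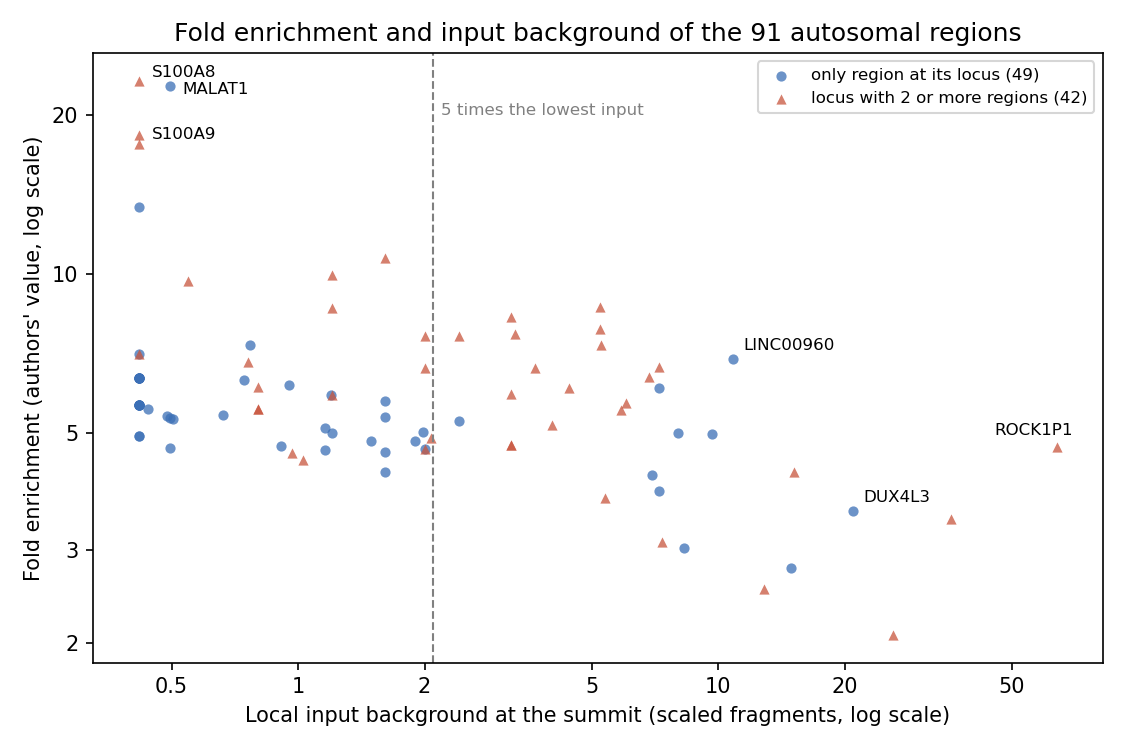
Fold enrichment as deposited (log scale) against the local input background recovered from it (scaled fragments at the summit, log scale), 1 point per autosomal region. Triangles are the 42 regions at loci with 2 or more regions, circles the other 49, and the dashed line marks 5 times the lowest input; S100A8, S100A9 and MALAT1 lie at the upper left, at 18.3-fold to 23.3-fold, and ROCK1P1 at the far right, at 4.70-fold.

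Regions lay closer together than uniform placement gave. The 91 regions fell into 60 loci, and 42 of them (46.2%, 35.6 to 56.9) had another region within 100000 bp. The 1000 uniform placements gave a mean of 0.666 and a maximum of 8 such regions (one-sided permutation test of positions, p = 0.001, the smallest they can give). The largest locus held 8 regions on chromosome 4 between 49280657 and 49333622, at least 291999 bp from the nearest annotated TSS, with enrichments of 4.74 to 7.87. Near ANKRD30BL and the microRNA gene MIR663B, 7 regions lay on chromosome 2 between 133012576 and 133031039, with enrichments of 2.07 to 7.34, and all 7 had raised input (12.6 to 62.3 times). At the end of chromosome 4, regions near the DUX4 repeat pseudogenes DUX4L6 and DUX4L4 had 7.70-fold and 6.63-fold enrichments, with 32 and 30 fragments. On chromosome 1 from 143278646, 3 regions within 5.25 kb had enrichments of 3.11 to 8.67.

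**Figure D2:**
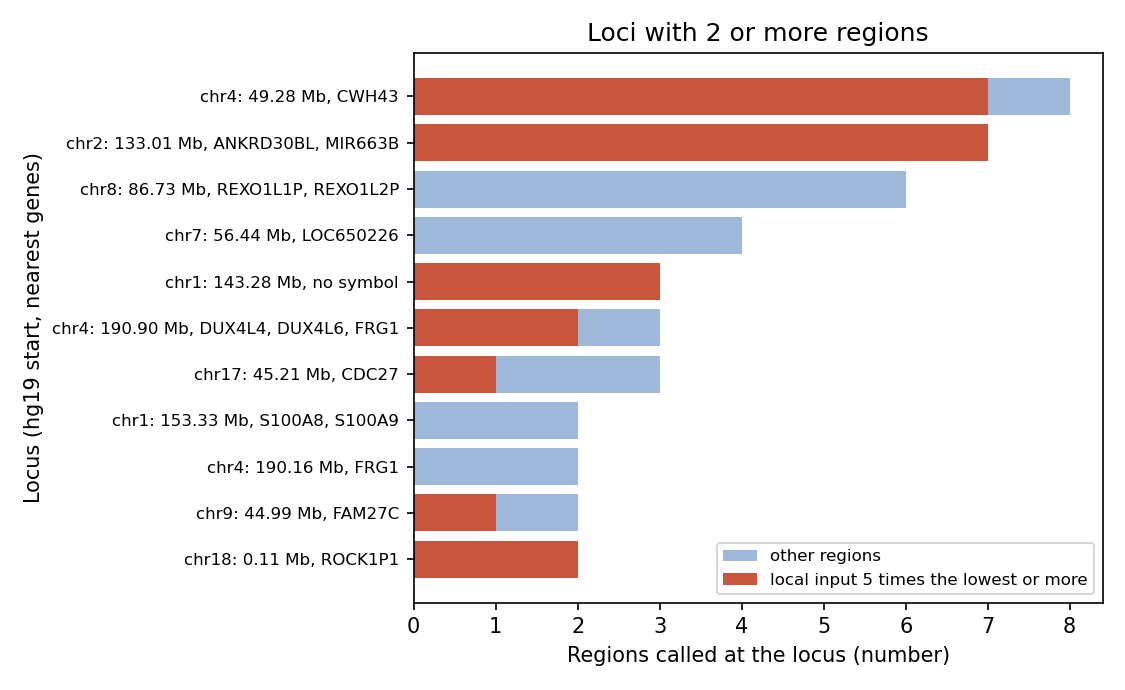
Number of autosomal regions called at each of the 11 loci with 2 or more regions, labelled by chromosome, hg19 start and nearest genes. The red part counts regions whose local input was at least 5 times the lowest; it takes 7 of 8 regions at the chromosome 4 locus from 49280657 and 0 of 6 at the REXO1L locus on chromosome 8.

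Distal intergenic sequence held 46 of 91 regions (50.5%, 39.9 to 61.2), promoters within 3 kb of a TSS held 21 (23.1%, 14.9 to 33.1), introns 17 (18.7%, 11.3 to 28.2) and exons 5 (5.49%, 1.81 to 12.4). The promoter class takes in both sides of a TSS and includes the S100A8, S100A9 and MALAT1 regions, which lie within their genes. A TSS lay within 1000 bp of 7 regions (7.69%, 3.15 to 15.2) and over 100000 bp away from 34 (37.4%, 27.4 to 48.1). The regions nearest to a TSS were at ROCK1P1 and USP17L15 (0 bp), DUX4L6 (75 bp), DUX4L4 (126 bp), REXO1L1P (149 bp), REXO1L2P (594 bp) and S100A8 (630 bp). USP17L15 rested on 6 fragments (2.20 to 13.1), and the REXO1L1P and REXO1L2P regions on 8 each (3.45 to 15.8). USP17L15, DUX4L6, DUX4L4, REXO1L1P and REXO1L2P belong to multicopy families, whose copies short reads do not always tell apart. Chromosome 4 held 20 regions at 10 loci and chromosome 1 held 13, also at 10 loci.

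**Figure D3:**
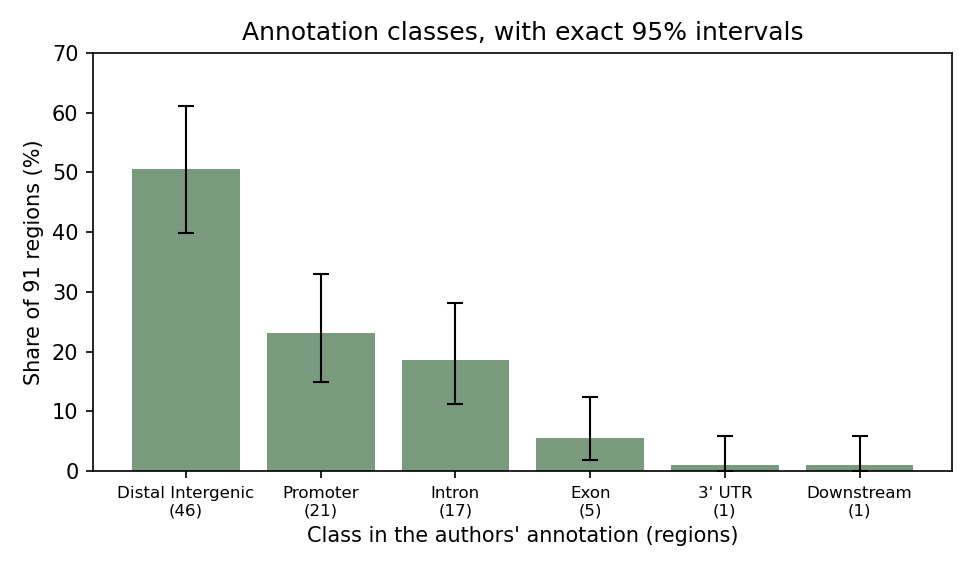
Share of the 91 autosomal regions in each class of the authors' annotation (percent), with exact 95% binomial intervals as bars and the number of regions in brackets. Distal intergenic regions make up 50.5% and promoter regions 23.1%. The intervals treat regions as independent.

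No gene of the fixed lists was the nearest gene of a region. The lists covered nuclear-encoded respiratory chain and mitochondrial ribosome genes, mitochondrial biogenesis and quality control, the antioxidant response, the integrated stress and unfolded protein responses, heat shock, ERK signalling with immediate early genes, translation with OLA1 itself, endothelial identity, apoptosis with DNA damage and cell cycle, hypoxia with glycolysis, inflammation, and chromatin regulators. They hold 455 matched genes, of which 0 were nearest to a region, against 0.449 expected by chance (exact hypergeometric p = 0.637 for so few). With the one-sided Fisher's exact test each of the 12 lists had a p of 1 before and after adjustment, so 0 lists had an unadjusted p under 0.05. A count of 0 among 56 nearest genes allows a share of up to 5.36%, taken as 3 counts of the 56. With 0.449 genes expected, a depletion of these lists was not detectable. Among the 56 nearest genes, 31 were protein-coding, 10 long non-coding RNA genes, 3 microRNA genes and 12 pseudogenes. The pseudogene share was 21.4%, against 27.7% of all autosomal genes in the table. That difference did not pass the test (Fisher's exact test, two-sided p = 0.370). Among regions with at least 10 fragments the difference had the opposite sign, with a share of 28.9%. The share among genes that the authors' annotation could assign is not known, so the test cannot show whether pseudogenes were enriched or depleted.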

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

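All shares and counts come from 1 library, so the alternatives show only how the choice of regions moves them. Those with a minimum of 10 fragments, other input levels, other neighbour distances and 1 gene per locus were chosen after seeing the data. Keeping only regions at or above the median −log10 q left 46 regions, and keeping folds at or above the median left 47, by construction. Widening the TSS limit to 5000 bp raised the share near a TSS from 7.69% to 25.3%. Counting loci in place of regions lowered chromosome 4 from 20 to 10, level with chromosome 1. Setting raised input at 2 times the lowest level raised its count from 33 to 57. Among the 63 regions with at least 10 fragments the share over raised input rose from 36.3% to 52.4%, by construction, since all 33 have over 10 fragments. The pseudogene share, below that of all genes in the full list (21.4% against 27.7%), lay above it among the regions with at least 10 fragments (28.9%, Fisher's exact p = 0.857), and the cause was not tested. Of the other 15 alternatives, 6 could not differ by construction: those on the identity and overlap of identical lists and those on gene lists with 0 genes. In the remaining 9 a share stayed within its 95% interval, a count within 1.5 times, or a test on its side of the threshold. These were the distal intergenic share (54.3% and 54.0%), the TSS share (8.70% and 6.35%), the grouping of regions (34 to 54 with a neighbour, p = 0.001 each by permutation of positions, and 57.1% in place of 46.2% with at least 10 fragments), raised input at 10 times (24), and the pseudogene share with 1 gene per locus (19.2%, Fisher's exact p = 0.215). Of these, the grouping share of 57.1% lay above the interval of the main share (35.6 to 56.9) and counts as unmoved only by its test. That test gave the smallest p its placements allow in every setting. Sequence motifs, random placements against the annotation and the test against chromosome length were planned and not run, since no hg19 genome was used here. Depth limits the list: 6 fragments was the lowest pileup called, and weaker sites would not appear in it. No paired analysis was possible because each group has 1 library and both lists are the same.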

Other observations

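All tests in this part were chosen after the list was seen. A group of 6 regions, 2 of them named by rule, lay on chromosome 8 between 86727524 and 86840022 near the pseudogenes REXO1L1P and REXO1L2P, with 8 to 11 fragments and enrichments of 4.44 to 6.81. On chromosome 7, 4 regions between 56438434 and 56441459 lay at least 74609 bp from the nearest start site, with enrichments of 4.65 to 6.65. NBPF9 and NBPF10 were each the nearest gene of a region of 7 fragments and a 5.64-fold enrichment, in exons that the authors' annotation gives to other genes. Regions near single genes were chosen here after their values were seen. VEGFC, a growth factor gene of lymphatic vessels, had a region 2701 bp upstream of its start with 10 fragments (4.80 to 18.4) and a 5.10-fold enrichment. UHRF2, a ubiquitin ligase gene, had a region with 13 fragments (6.92 to 22.2) and a 4.82-fold enrichment over an input 4.55 times the lowest level. It lay 1448 bp from the start of the 1 transcript that the authors' annotation assigned, which need not be the start of the gene. KRT1, which encodes a keratin of the upper epidermis, had a region in its 3′ UTR with 13 fragments. Its enrichment was 5.37-fold over an input 3.85 times the lowest level. MTIF3, a mitochondrial translation initiation factor gene, was the nearest gene of an intergenic region 8965 bp away with 31 fragments and a 3.89-fold enrichment over an input 17.3 times the lowest level.

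For the grouping of regions at loci, uniform placement over the genome is excluded, since 42 of 91 regions had a near neighbour and no placement gave more than 8. Sequence present in more copies in the cells than in hg19 may account for part of it. Loci with 2 or more regions had a median input 4.27 times that of single-region loci (11 against 49 loci, permutation p = 0.0277). The ratio stayed between 3.34 and 4.48, with permutation p up to 0.0472, when each locus was left out. Raised input was not shared by all of these 11 loci. Their medians ran from the lowest level itself (S100A8 with S100A9) and 1.92 times it (REXO1L) to 119 times it (ROCK1P1). More copies alone, recovered equally by immunoprecipitation and input, was examined at the 33 raised regions, at bounds corrected for every fragment-sized window. Pileup and input stayed apart at 4 of them, both at ROCK1P1, LINC00960 and chromosome 1 from 143278646. The margin was wide only at the first ROCK1P1 region (212 against 98.9 fragments), where more copies alone is argued against. At these 4 the background was a whole number of ends. The input bound took them as independent counts, so it can be too low. Narrower margins at LINC00960 (38.6 against 28.6), the second ROCK1P1 region (69.9 against 63.3) and chromosome 1 (20.6 against 19.4) therefore do not decide. LINC00960 is also the only region at its locus, outside the grouping. For the other 29, these bounds do not tell more copies alone apart from enrichment, and the caller selected regions with a high ratio. In some of them, such as DUX4L6, DUX4L4, LINC00273 and several at ANKRD30BL, the background was not a whole number of ends. It therefore came from a wider window with more ends, while the bound counted ends in a fragment-sized window. The input bound can be too high there, and bounds for the wider windows were not computed. Whether pileup and input stay apart at those regions was thus not decided. Binding by OLA1 and unequal recovery of repeats in the 2 libraries stay open, since no IgG or control list was compared.

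The 5 regions with at least 10-fold enrichment over background input form a second pattern, and the 3 genic ones lie 11 bp (S100A8), 56 bp (S100A9) and 6716 bp (MALAT1) from the 3′ ends of their genes. DNA copies of transcripts from other cells, such as keratinocytes or neutrophils, are a candidate explanation. DNA copies of annotated transcripts are argued against as the whole cause, since 2 of the 5 lie outside annotated genes. Both lie over 100000 bp from the nearest annotated start site. Copies of unannotated transcripts stay open there, and these 2 regions do not bear on the 3 genic ones. For DNA copies of transcripts, genic regions cannot be told apart from binding. Regions lay at 3 of 15 keratinocyte and 2 of 12 neutrophil genes, which share S100A8 and S100A9. MALAT1 is on neither list, so these lists do not bear on its region. Of the 23 other genes only KRT1 (1 gene, 0.0207 expected by chance) had a region, 130 bp from its 3′ end. That excess has no test, since the gene lists were written after the KRT1 region was seen. The KRT1 region is itself outside the pattern, with a 5.37-fold enrichment over an input 3.85 times the lowest level. Signal below the calling limit is not in a list of called regions. Binding of OLA1 at the genic regions was not tested and stays open.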
